A study of Mus musculus with 4 samples.

How the data were processed

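Single-cell RNA sequencing was made of the ventral prostate of C57BL6j mice, 2 from a sham group and 2 from a group coded te2, harvested 2 weeks after pellets were implanted. The code te2 is not spelled out in the sources used here. The labels describe a series on an imbalance of steroid hormones. Per the labels' protocols, the paired lobes of each animal went into 1 tube, were dissociated in the cold with a bacterial protease and strained, and 7000 cells per sample were loaded on a droplet platform that tags the 3' end of each transcript with a unique molecular identifier (UMI). Each library is 1 animal.

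The deposited tables hold raw UMI counts per gene and cell, which the authors made with kallisto 0.46.1, bustools 0.39.4, R 4.3.2 and Seurat 5.0.1 on genome build GRCm39, per the submitters' processing notes. These notes give no role for each tool. The values show that each table keeps genes seen in at least 3 cells of its library and cells with at least 196 to 199 genes. A gene missing from a library's table was entered as 0 there, so such a 0 can stand for up to a few counts that were removed before deposit. Genes keep the symbols of the tables. The genome given with the data is an earlier build, GRCm38, so no coordinates were taken from it. Genes with near-identical copies, such as Smr2 and Smr2l, Sbp and Sbpl, and the pseudogenes Ccdc50-ps and Rps2-ps10, are uncertain, since the sources used here do not say how reads shared between copies were counted.

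The 4 tables hold 11245 cells and 17896 genes in all. Totals were 3999690 and 5513275 UMIs in the sham libraries and 12259610 and 13134017 in the te2 libraries. Cells were kept with at least 500 UMIs, at least 200 genes and at most 20% mitochondrial counts, which left 8091. Doublets were called per library with scrublet as run by scanpy 1.11.5, and the 97 called (1.20%) were left out, which left 7994 cells. Counts were scaled to 10000 per cell and log-transformed, and cells were clustered from 2000 variable genes, 30 principal components and 15 neighbours with the Leiden method at resolution 1 (igraph 0.11.9, scikit-learn 1.9.0), without integration of the libraries.

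No cell annotation was used here, so classes were rebuilt from marker lists. Each cluster took the class with the highest mean marker excess. It stayed unnamed with fewer than 3 detected markers, with more markers of another class than of its own among its top 10 genes by fold, or with low UMIs and no marker among those genes. The markers were fixed before the data were examined, as were the tests, the gene lists and the rule for named genes. The details of the naming rule were set after the data were seen. Marker genes reported within a class are named as such. Psca, Krt7, Krt19, Wfdc2 and Clu belong to the proximal luminal markers. Krt5, Krt14, Krt15 and Dsc3 belong to the basal markers. Sbp and Spink1 belong to the luminal markers. The clusters left unnamed held 38.7% and 24.0% of the kept sham cells and 9.86% and 13.4% of the kept te2 cells.

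Raw counts were summed per library and class, and te2 was tested against sham with the quasi-likelihood test of edgeR 4.0.16 (TMM factors, the default filter on low counts, two-sided, Benjamini-Hochberg adjustment, FDR 0.05). A class was tested with at least 20 cells in every library. T cell-like and lymphatic endothelial-like cells fell short of that. Expression is given as CPM, a gene's count scaled by the total of its class's summed counts in that library times its TMM factor. Lower bounds, ratios of counts and levels set against other classes or all cells are scaled by totals alone, except where Wfdc3 is compared between classes. Errors beside a log2 change, or a difference of such changes, are standard errors derived from the test. Each is the absolute value over the square root of its F statistic. Errors beside a mean CPM or share are SDs over 2 libraries. For a group at 0 counts, a lower bound of the fold was computed against a floor of 3 counts over the libraries of that group whose tables list the gene, and none was given where neither does. With 1 to 3 counts, the ratio of the summed counts is given with its exact 95% interval, which covers counting error only. Lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, beside camera with an estimated correlation and fry, over 25 lists. Shares of cells were tested with edgeR on cell numbers, with exact 95% binomial intervals that cover counting error only. The difference of response between classes was tested in edgeR as the term of class and treatment, with the library as a block. With 2 libraries against 2, an exact permutation test cannot go below p = 0.333. The far smaller p-values of edgeR rest in large part on a spread pooled over genes. They do not measure how far each gene varies between animals.

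For the luminal class the named genes are the 12 rising and 12 falling genes of largest change among those past FDR 0.05, with a mean log2 CPM of at least 5 and no overlap between the groups. For the other classes they are 6 each way, for lists up to 4 members of smallest p, and for differences between classes 5 each way. Genes with only a clone or predicted name and mitochondrially encoded genes are counted but not named. Hormone receptor genes are given whatever their change. Some genes that these rules name are not reported here.

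The steps were tested on simulated data drawn from the real means and library sizes, with 200 changed genes in each of 5 draws. Of the genes changed 2-fold, the test recovered 64.9% in luminal (10835 genes), 34.9% in proximal luminal (10557), 27.9% in basal (7838), 25.1% in fibroblast (4001) and 10.7% in macrophage sums (2268). Of the genes changed 4-fold it recovered 95.0%, 79.4%, 80.1%, 88.4% and 80.2%. False calls made up 7.09%, 4.99%, 5.51%, 6.83% and 4.83% of calls. In all cells summed (13752 genes) recovery was 40.0% and 85.4%, and false calls made up 10.7%. A raised list was found in 5 of 5 draws with the preset correlation and in 0 of 5 with the estimated one, in every class and in all cells summed. The simulated genes varied independently of each other, so these draws do not cover lists whose members vary together. Shares were simulated apart from these, from the pooled sham shares, with a spread and a number of cells that were set and not taken from the data. The weight of basal cells was raised 4-fold before shares were rescaled, so their share rose by less and the other shares fell. The rise was found in 68 of 100 draws. Other classes held 30.6% of the calls, which are thus not all false.

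Libraries of one group were compared with each other before they were averaged. Their counts differed by more than sampling noise in every tested class, with a chi-square per degree of freedom from 1.78 in basal sham sums to 10.7 in luminal te2 sums, so each counts as 1 replicate. Alternatives covered DESeq2 1.42.0, scaling without TMM factors, filters on genes and cells, cluster resolution, classes by marker score, thinning to equal totals, secreted products left out, the replicate number as a block and each library left out in turn. Other tools were R 4.3.3, anndata 0.12.19, numpy 2.4.6 and pandas 2.3.3.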

Results

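The ventral prostates of 2 sham mice and 2 te2 mice were compared by single-cell RNA sequencing. The sham libraries held 2250 and 3061 cells with a median of 828 and 917 UMIs per cell. The te2 libraries held 3078 and 2856 cells with a median of 2296.5 and 2671.5 UMIs. After filtering, 1620 and 2002 sham cells and 2291 and 2081 te2 cells were kept. They included cells that were luminal-like, proximal luminal-like, basal-like, fibroblast-like, macrophage-like, T cell-like and lymphatic endothelial-like, called by those names without the suffix from here on. The median depth per cell was higher in both te2 libraries than in both sham libraries in every class. In luminal cells it was 4204.5 and 3330 UMIs in sham and 8225.5 and 10707.5 in te2.

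**Figure D1:**
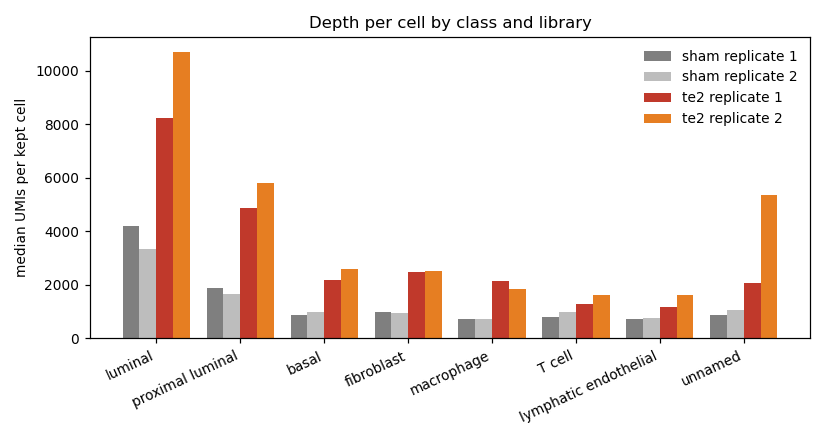
Bars give the median number of UMIs per kept cell (vertical axis, from 0) for each cell class and each of the 4 libraries. The te2 bars stand above the sham bars in every class, in luminal cells at 8225.5 and 10707.5 against 4204.5 and 3330.

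The first comparison asked how luminal cells, the secretory epithelium of the gland, differed between te2 and sham. Of the 12 named rising genes, 3 had no counts in sham, and the others had 3 to 92. Psca, which encodes a surface antigen of prostate epithelium and is one of the proximal luminal markers, had no counts in sham luminal cells and reached 628 ± 205 CPM (SD, n = 2) in te2. The table of sham replicate 1 does not list Psca. Against sham replicate 2 the rise was at least 729-fold. Ly6c1, a surface protein of the Ly6 family, had no sham counts and reached 87.9 ± 19.5 CPM, at least 176-fold higher. Smr2l reached 106 ± 62.6 CPM and is in neither sham table, so no bound is given. Lcn2, which encodes the iron-siderophore binder lipocalin 2, had 3 counts in sham and 549 in te2, a ratio of 120 (95% interval 40.9 to 584).

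Other named genes that rose in luminal cells were Fxyd4, a regulator of the sodium-potassium pump, by a log2 change of 6.52 ± 0.66, Saa1, which encodes the acute phase protein serum amyloid A, by 5.89 ± 0.32, and Krt7, a keratin and proximal luminal marker, by 5.46 ± 0.20. Ly6a rose by 5.16 ± 0.22, Lrg1 by 4.90 ± 0.26, the annexin gene Anxa3 by 4.55 ± 0.28, Olfml3 by 4.51 ± 0.34 and Ahnak, which encodes a large scaffold protein, by 4.29 ± 0.19. Krt7 stood at 3.97 ± 0.98 CPM in sham and 171 ± 6.96 CPM in te2.

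The named falling genes of luminal cells included ion channels, transcription factors and a metallothionein. Itpripl2 had the steepest fall, with a log2 change of -6.09 ± 0.22. The potassium channel gene Kcnk3 changed by -3.48 ± 0.17 and the calcium channel gene Trpv6 by -2.37 ± 0.13. The transcription factor genes Creb5 and Bhlha15 changed by -3.18 ± 0.25 and -2.44 ± 0.14. Mt1, which encodes a metal-binding metallothionein, went from 5460 ± 682 CPM in sham to 1268 ± 241 CPM in te2. Scgb2b7 (-2.32 ± 0.34), the chymotrypsin gene Ctrc (-2.23 ± 0.16), Yeats2 (-2.16 ± 0.17), the growth factor gene Tgfb2 (-2.09 ± 0.16), the splicing factor gene Nova1 (-1.96 ± 0.18) and Fam25c (-1.85 ± 0.14) also fell. The adjusted p of these 24 genes lay between 4.67e-10 for Krt7 and Itpripl2 and 0.000134 for Scgb2b7, by edgeR's quasi-likelihood test.

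**Figure D2:**
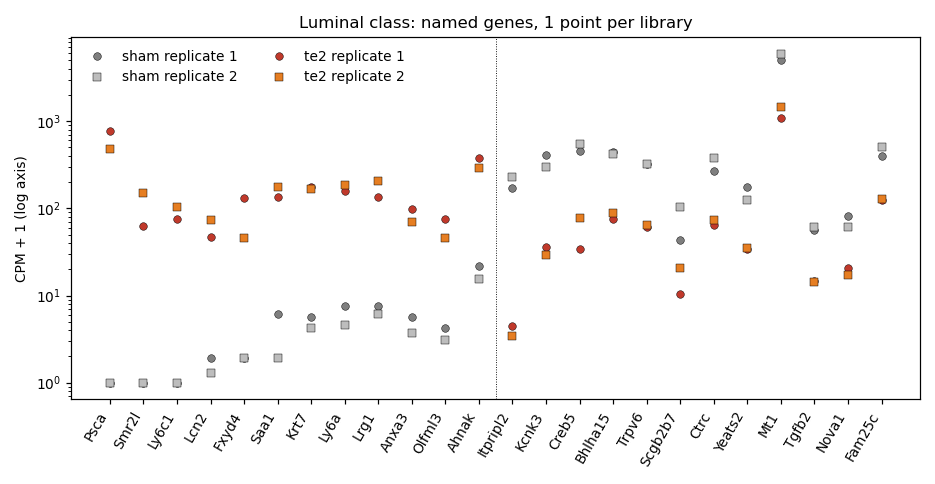
Points give the CPM plus 1 (vertical log axis) of the 12 named rising and 12 named falling genes in the summed luminal cells, 1 point per library. The sham and te2 points do not overlap for any of these genes, which the rule for naming them required, and Mt1 lies at 5460 CPM on average in sham and 1268 in te2.

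In all, 3579 of the 11004 genes tested in luminal cells passed the test, 1955 higher and 1624 lower in te2. The luminal cells of the groups fell mostly into different clusters. The cluster led by Mat2a, Sbp and Mt1 held 489 and 810 cells of the sham libraries and 6 and 10 of the te2 libraries, and the one led by Gpx3, Wfdc3 and Oxct1 held 7 and 18 of sham and 409 and 408 of te2. Psca is among the top genes of the latter, and Mt1, Fam25c, Creb5, Trpv6, Kcnk3 and Bhlha15 are among those of the former. The count was 1806 with DESeq2, 2265 without te2 replicate 1 and 1962 without te2 replicate 2. Without TMM factors the split was 2382 higher and 1181 lower.

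The estrogen receptor genes Esr2 (log2 change -0.87 ± 0.41, adjusted p = 0.125) and Esr1 (-0.02 ± 0.31, 0.968) and the prolactin receptor gene Prlr (-0.09 ± 0.13, 0.66) did not pass the test in luminal cells. The fall of Esr2 in luminal cells passed under 4 alternatives, such as without sham replicate 1 (-1.21, adjusted p = 0.0445), and was -0.16 without sham replicate 2.

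Of the 24 fixed lists with enough measured members, 9 passed camera in luminal cells. In the acute phase and innate defence list, 7 of 9 measured members rose and 0 fell, both over all genes and adjusted over the list alone, with Saa1, Lcn2, Wfdc2 (log2 change 3.53 ± 0.40) and Lbp (3 counts in sham and 84 in te2, ratio 18.4, 95% interval 6.07 to 90.8) of smallest p (camera adjusted p = 0.000316; adjusted p = 0.673 with an estimated correlation). In the list of keratins and luminal-basal identity, which shares Psca and Ly6a with the castration-induced list, 9 of 18 rose and 1 fell (9 and 1 adjusted over the list alone), with Krt7, Psca and Ly6a among the members of smallest p (camera adjusted p = 0.00112; adjusted p = 0.673 with an estimated correlation). In the castration-induced list 7 of 11 rose and 3 fell, counts that were the same adjusted over the list alone. Clu rose by 3.16 ± 0.22 and Anxa1 by 2.43 ± 0.18 (adjusted p = 0.0163; adjusted p = 0.711 with an estimated correlation). Markers of proximal luminal cells moved with these 3 lists. Krt7, Psca, Wfdc2 and Clu are among the markers fixed for those cells. Scaled by totals alone, Wfdc2 stood at 95.8 and 52.8 CPM in the luminal cells of the te2 libraries and at 1541 and 1156 in their proximal luminal cells, Clu at 809 and 906 against 1276 and 2438, and Anxa1 at 546 and 417 against 1079 and 1063.

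Of 34 oxidative phosphorylation genes, 19 rose and 3 fell in luminal cells (21 and 4 adjusted over the list alone), among them Ndufa4 (1.28 ± 0.14), Cycs (1.02 ± 0.13), Cox5a (1.02 ± 0.14) and Cox5b (0.94 ± 0.12), with a camera adjusted p of 0.000117. Of 20 glycolysis and hypoxia genes, 12 rose and 1 fell (12 and 1 adjusted over the list alone), with Pgk1 (1.28 ± 0.13), Ldha (1.22 ± 0.13) and Pkm (1.16 ± 0.14) as examples and an adjusted p of 0.000711. Both lists had an adjusted p of 0.711 with an estimated correlation.

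Of 33 cell cycle genes, 10 rose and 0 fell (15 and 0 adjusted over the list alone), with Stmn1 (1.99 ± 0.31), Tyms (1.41 ± 0.25), Cdk1 (1.73 ± 0.36) and Pcna (0.69 ± 0.17) of smallest p (adjusted p = 0.0134; adjusted p = 0.764 with an estimated correlation). Of 15 genes of MHC class I presentation, 7 rose and 1 fell (7 and 1 adjusted over the list alone), with H2-K1 (1.47 ± 0.14), the immunoproteasome gene Psmb8 (1.71 ± 0.19) and H2-D1 (1.07 ± 0.13) as examples and an adjusted p of 0.0134. Of 24 genes of the immediate early and dissociation stress list, 9 rose and 0 fell (10 and 0 adjusted over the list alone), led by the chaperone genes Hspd1 (133 ± 5.34 CPM in sham and 266 ± 2.73 in te2), Hspe1 (log2 change 0.84 ± 0.13) and Hspa8 (0.94 ± 0.17), with an adjusted p of 0.0163. Interferon response genes went the other way, with 6 of 24 lower and 1 higher (5 and 1 adjusted over the list alone), among them Stat2 (-1.34 ± 0.14), Rsad2 (-3.79 ± 0.60), Ifit1 (-1.45 ± 0.26) and Mx1 (-1.56 ± 0.34), with an adjusted p of 0.0493. These 3 lists had an adjusted p of 0.711 with an estimated correlation. The stress and interferon calls were each lost under 5 alternatives, and the cell cycle call under 4.

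The list of androgen-regulated prostate genes did not pass camera in luminal cells, with 7 of 23 higher and 4 lower (7 and 5 adjusted over the list alone; adjusted p = 0.53). The median of its members was below 0 and their mean above it. Estrogen response genes did not pass either, with 4 of 15 higher and 0 lower (2 and 0 adjusted over the list alone; adjusted p = 0.318).

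**Figure D3:**
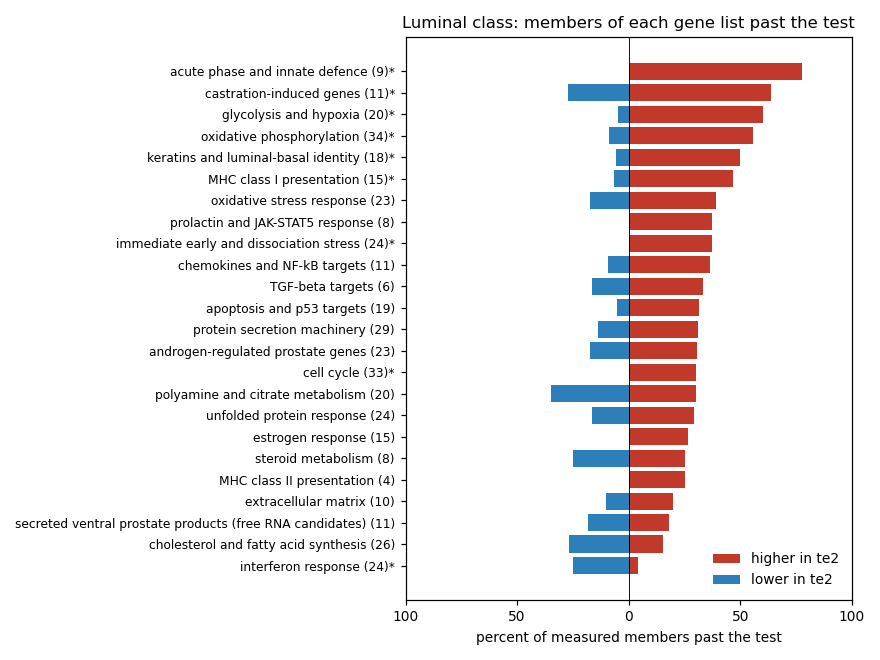
Bars give the percent of each list's measured members past the per-gene test in luminal cells, lower in te2 to the left and higher to the right. The measured number is in brackets and an asterisk marks the 9 lists past camera with the preset correlation, such as acute phase and innate defence with 7 of 9 members higher.

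The second comparison took proximal luminal cells, named from markers of the epithelium nearest the urethra. Smr2l, which had no counts in sham and is in neither sham table, reached 1565 ± 259 CPM in te2. Smr2 reached 769 ± 428 CPM, Dmbt1, which encodes a mucosal defence protein, 78.8 ± 22.8 CPM and Ltf, the lactoferrin gene, 46.7 ± 1.69 CPM, and these are also in neither sham table. Saa1 had 0 counts in sham and 403 ± 302 CPM in te2, at least 82.5-fold higher. Ly6c1 had 3 counts in sham and 3789 in te2, a ratio of 92.3 (95% interval 31.6 to 448). The carbonic anhydrase gene Car2 fell (-3.67 ± 0.34), from 115 and 463 CPM in the sham libraries to 22.8 and 31.9 CPM in te2. The other named falling genes were the uroplakin gene Upk1a (-2.84 ± 0.15), the transcription factor gene Meis2 (-2.62 ± 0.22), Igfbp5 (-2.60 ± 0.22), Naip5 (-2.32 ± 0.21) and Creb5 (-1.97 ± 0.28). The adjusted p of these genes lay between 1.46e-07 for Smr2l and Upk1a and 0.00152 for Saa1. Prlr rose by 2.22 ± 0.22, from 50.5 ± 19.8 to 265 ± 8.14 CPM (adjusted p = 3.77e-05), while Esr1 (0.93 ± 0.65, adjusted p = 0.405) and Esr2 (-1.51 ± 0.86, 0.298) did not pass.

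In proximal luminal cells 1096 of 10848 genes passed, 556 higher and 540 lower. The acute phase list had 6 of 10 members higher and 0 lower, among them Lcn2, at 14.1 ± 5.76 CPM in sham and 239.8 ± 28.9 in te2, and Lbp (3.74 ± 0.43). The secretion machinery list had 7 of 29 higher and 0 lower (11 and 1 adjusted over the list alone), with the translocon genes Sec61b (1.32 ± 0.20) and Ssr4 (1.06 ± 0.18). The unfolded protein response list had 9 of 24 higher and 0 lower (11 and 0 adjusted over the list alone), with the chaperone genes Calr (1.08 ± 0.17) and Hspa5 (1.01 ± 0.22). The immediate early and dissociation stress list had 6 of 23 higher and 0 lower (Jund 1.27 ± 0.20), and the estrogen response list 6 of 15 higher and 0 lower (6 and 1 adjusted over the list alone), among them Prlr, Ltf, Krt19 (1.37 ± 0.23) and Nrip1 (0.82 ± 0.16). The acute phase and stress counts were the same adjusted over the list alone. These 5 lists passed camera (adjusted p = 3.25e-06, 2.21e-05, 2.21e-05, 0.00307 and 0.0103), with an adjusted p of 0.653 to 0.732 with an estimated correlation.

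Most sham proximal luminal cells lay in a cluster led by Nxpe2, Cyp2f2 and Car2 (74 and 230 sham, 52 and 31 te2 cells), and most te2 cells in clusters led by Fxyd4 and Clu (0 and 0 sham, 344 and 305 te2) and by Smr2 and Smr2l (2 and 1 sham, 487 and 254 te2). Saa1, Ly6c1, Car2 and Upk1a are also among the top genes of these clusters. In the cluster led by Nxpe2, Prlr had too few counts to be tested (6 and 32 in sham, 16 and 2 in te2). The count of 1096 became 187 within the shared cluster, an alternative added after the data were seen whose te2 cells were shallow (median 658.5 and 656 UMIs against 1912 and 1668.5 in sham), 539 with DESeq2, 348 with sums thinned to equal totals, 517 without sham replicate 2 and 617 without te2 replicate 2.

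In basal cells, the layer that underlies the luminal epithelium, transcripts of luminal secretory products fell. Spink1, a protease inhibitor gene and luminal marker, changed by -3.76 ± 0.25 (adjusted p = 1.64e-17) and Sbp, the spermine binding protein gene, by -3.21 ± 0.26. Ccdc50-ps (-3.70 ± 0.38), the chloride cotransporter gene Slc12a2 (-2.83 ± 0.20), the Fc receptor gene Fcgr2b (-2.82 ± 0.39) and Rps2-ps10 (-2.77 ± 0.37) also fell. By totals alone, Slc12a2 stood in basal cells at 0.253 (sham) and 0.0393 (te2) times its level in all cells. Spink1 stood at 0.220 and 0.0469 times, while Ccdc50-ps, Fcgr2b and Rps2-ps10 lay above their levels in all cells. The 6 named rising genes had 0 or 1 count in sham. Hs3st1 went from 0 to 46.2 ± 2.78 CPM (in the table of only 1 sham library, against which it was at least 3.74-fold higher), Ercc1, a DNA repair gene, from 0 to 34.2 ± 6.28 CPM (at least 3.82-fold higher), and the desmosome gene Dsc3, a basal marker in neither sham table, from 0 to 39.1 ± 26.2 CPM. The heat shock gene Hspa1a had 1 count in sham and 122 in te2 (ratio 17.5, 95% interval 3.08 to 696), Smox 1 and 100 (14.3, 2.51 to 572) and Cbr3 1 and 89 (12.8, 2.23 to 510). Prlr changed by -1.70 ± 0.59 (adjusted p = 0.0464, lost under 8 alternatives) and Esr1 by -1.48 ± 0.57 (0.081, not past the test). Basal Prlr stood at 0.164 (sham) and 0.0474 (te2) times its level in all cells by totals alone. Whether Slc12a2 and Prlr in basal cells come from free RNA was not tested.

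Of 8295 genes tested in basal cells, 973 passed, 544 higher and 429 lower. Of the keratins and luminal-basal identity list, 8 of 22 rose and 2 fell (11 and 2 adjusted over the list alone), with the basal markers Krt15 (2.40 ± 0.23) and Krt14 (2.43 ± 0.25) and with Ly6a (2.99 ± 0.33) higher and Krt8 lower (-0.94 ± 0.18). Of the secreted products, 5 of 7 fell and 1 rose, the same adjusted over the list alone. Oxidative phosphorylation genes rose in 8 of 34 and fell in 0 (10 and 1 adjusted over the list alone), with Ndufa4 (1.36 ± 0.20) and Cox5a (1.33 ± 0.22) as examples. Oxidative stress genes rose in 7 of 21 and fell in 0 (9 and 0 adjusted over the list alone), with the peroxiredoxin gene Prdx1 (1.30 ± 0.19) and the ferritin gene Ftl1 (1.10 ± 0.19) as examples. These 4 lists passed camera (adjusted p = 0.000291, 6.53e-11, 0.000291 and 0.0118), as did secretion machinery (7 of 26 higher, 1 lower; 8 and 1 adjusted over the list alone; 0.00528), androgen-regulated genes (3 of 20 higher, 6 lower; 5 and 6 adjusted over the list alone; 0.0401), unfolded protein response (3 of 19 higher, 0 lower; 5 and 1 adjusted over the list alone; 0.0401) and cholesterol and fatty acid synthesis (0 of 16 higher, 1 lower, the same adjusted over the list alone; 0.0471). With an estimated correlation the adjusted p of the 8 lists was 0.361 to 0.608, and over all alternatives the cholesterol call was lost under 8 and the androgen call under 6. Of the androgen-regulated members of smallest p, Spink1, Sbp and Msmb (-2.96 ± 0.48) encode secreted products and Tsc22d1 rose (1.42 ± 0.26).

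The basal cells of sham lay mainly in a cluster led by Col18a1, Tgm2 and Cp (92 and 231 sham, 4 and 4 te2 cells), with 0 of the basal markers among its top 10 genes, and those of te2 in one led by Krt15, Lgals7 and Krt5 (0 and 3 sham, 484 and 506 te2), with 4 among them. The count of 973 became 248 with DESeq2, 279 with thinned sums, 331 with classes by marker score, 367 without sham replicate 2, 544 without te2 replicate 1 and 336 without te2 replicate 2, and the split was 681 higher and 267 lower in basal cells without a filter on low counts.

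In fibroblasts 113 of 4404 genes passed, 46 higher and 67 lower. The complement gene C7 rose by 3.57 ± 0.30 (adjusted p = 6.4e-05), Bmper, a modulator of BMP signalling, by 3.04 ± 0.49, Wfdc3 by 2.86 ± 0.49 and the angiopoietin gene Angpt4 by 2.43 ± 0.41. Wfdc3 is a top gene of the te2 luminal cluster. It stood at 118 and 184 CPM in the fibroblasts of the te2 libraries, a level 0.0416 times that in all te2 cells by totals alone, against 140 and 76.5 CPM in their basal cells, 175 and 223 in macrophages and 4508 and 4514 in luminal cells. Hp, the haptoglobin gene, is in neither sham table and reached 199.1 ± 99.2 CPM. Ctla2a had 3 counts in sham and 257 in te2, a ratio of 58.2 (95% interval 19.7 to 284), with 678 ± 729 CPM in te2. The hemoglobin genes Hbb-bs (-3.91 ± 0.63) and Hba-a2 (-3.25 ± 0.57), the secreted product genes Spink1 (-3.48 ± 0.38) and Sbp (-3.44 ± 0.43), the transcription factor gene Bhlhe41 (-3.20 ± 0.51) and Smpd3 (-2.89 ± 0.47) fell. Hbb-bs stood at 493 and 79.0 CPM in the sham libraries and at 28.0 and 18.4 CPM in te2. Prlr (0.30 ± 0.39, adjusted p = 0.758) did not pass.

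Of the extracellular matrix list, 3 of 31 members rose in fibroblasts and 0 fell (6 and 0 adjusted over the list alone), namely the collagen genes Col5a2 (1.49 ± 0.22) and Col6a3 (1.48 ± 0.26) and the elastin gene Eln (1.48 ± 0.36), with a camera adjusted p of 0.00108. The acute phase list had 3 of 6 higher (3 adjusted over the list alone), namely Hp, Lbp (1.66 ± 0.31) and C3 (1.05 ± 0.22), with an adjusted p of 0.0278. Of the estrogen response list, 2 of 9 rose (3 adjusted over the list alone), C3 and Igf1 (0.92 ± 0.22), with an adjusted p of 0.0278. Also past camera were secreted products (0 of 5 higher, 3 lower; 0 and 4 adjusted over the list alone; 0.000138), unfolded protein response (1 of 18 higher, 3 adjusted over the list alone; 0.00053), immediate early and dissociation stress (1 of 16, 4 adjusted over the list alone; 0.00356), secretion machinery (0 of 28, 1 adjusted over the list alone; 0.0278), castration-induced genes (0 of 13, 6 adjusted over the list alone; 0.0278) and prolactin response (1 of 4, 1 adjusted over the list alone; 0.0314). With an estimated correlation the adjusted p of the 9 lists was 0.428 to 0.473, and the prolactin call was lost under 6 alternatives.

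The fibroblasts of sham lay mainly in a cluster led by Serping1, Gsn and Plac9 (228 and 84 sham, 7 and 20 te2 cells) and those of te2 in one led by Col3a1, Gsn and Col1a2 (1 and 0 sham, 72 and 99 te2). The fibroblast count rested on both sham libraries, since edgeR called 0 genes without sham replicate 1 (443 at an unadjusted p under 0.05), 1 without sham replicate 2 and 205 without te2 replicate 1. DESeq2 on all 4 libraries called 62 genes, and thinned sums gave 35.

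In macrophages the named rising genes were Fabp5, Gpnmb, Spp1, Clec4d, Smr2 and Atp6v0d2. Fabp5, a fatty acid binding protein gene, had 2 counts in sham and 2845 in te2, a ratio of 253 (95% interval 70.1 to 2094). Gpnmb, a lysosome-associated glycoprotein gene, had 0 counts in sham and reached 3090 ± 526 CPM, at least 81.0-fold higher. Spp1, the osteopontin gene, reached 9057 ± 4516 CPM, Clec4d, a lectin receptor gene, 206 ± 0.782 CPM and Smr2 198 ± 26.6 CPM, and these are in neither sham table. Smr2 leads a te2 proximal luminal cluster, and its level in te2 macrophages was 0.448 times that in all te2 cells by totals alone. Atp6v0d2, a subunit gene of the vacuolar proton pump, is in the table of 1 sham library and was at least 5.23-fold higher than there. Spn, which encodes the leukocyte surface protein sialophorin, changed by -4.64 ± 0.55, Spink1 by -4.57 ± 0.46, Ccdc50-ps by -4.42 ± 0.55, Hba-a1 by -4.27 ± 0.59 and Hbb-bs by -3.44 ± 0.60. Il2ra had 14 counts in sham and 3 in te2, a ratio of 0.0382 (95% interval 0.00703 to 0.137) after scaling by the totals.

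Of 2624 genes tested in macrophages, 307 passed, 148 higher and 159 lower. Glycolysis genes rose in 7 of 12 and fell in 0, the same adjusted over the list alone (Aldoa 2.63 ± 0.42, Pkm 2.40 ± 0.46, Gapdh 1.73 ± 0.38; camera adjusted p = 0.000444). Oxidative stress genes rose in 5 of 12 and fell in 0 (7 and 1 adjusted over the list alone), with Ftl1 (2.10 ± 0.40) and Prdx1 (1.61 ± 0.34) as examples (adjusted p = 0.00428). The immediate early and dissociation stress list had 2 of 10 higher and 0 lower (3 and 0 adjusted over the list alone), Atf3 (2.22 ± 0.54) and Klf2 (1.59 ± 0.43; adjusted p = 0.0151). Androgen-regulated genes fell in 3 of 4 (4 adjusted over the list alone; adjusted p = 4.5e-05) and secreted products in 3 of 4 (3 adjusted over the list alone; adjusted p = 0.000172). Both of these lists hold Spink1 and Sbp (-3.35 ± 0.60). With an estimated correlation the adjusted p of all 5 lists was 0.557, and the stress call was lost under 5 alternatives.

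A macrophage cluster led by Spp1, Fabp5 and Lyz2, with Gpnmb among its top genes, held 3 and 0 sham and 50 and 12 te2 cells. Most sham macrophages lay in the one led by Cd74, Ms4a7 and C1qc (35 and 49 sham, 27 and 34 te2). Without the Spp1 cluster, an alternative added after the data were seen, 158 genes passed, 99 of them among the 307, and none of the 6 named rising genes passed the filter on low counts. The count was 80 with DESeq2 (51 higher, 29 lower), 146 with thinned sums, 193 without sham replicate 2, 107 without te2 replicate 1 and 157 without te2 replicate 2. Without TMM factors, 137 were higher and 230 lower in macrophages, where the split was 145 and 32 at 10 CPM or more and 280 and 60 without a filter on low counts, and 68 were higher and 57 lower in fibroblasts.

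**Figure D4:**
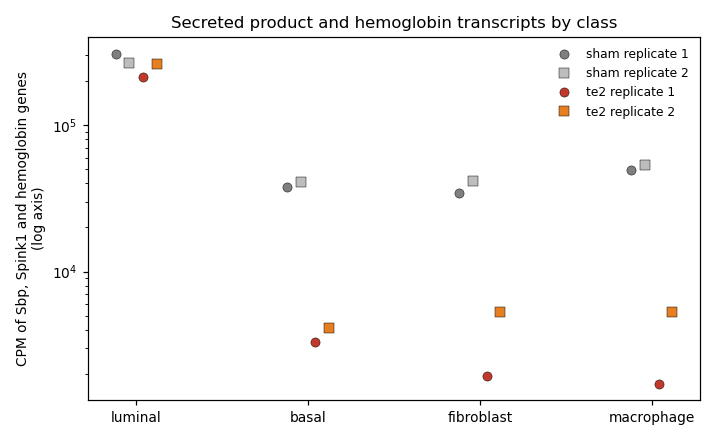
Points give the summed CPM, scaled by totals alone, of Sbp, Spink1 and the hemoglobin genes (vertical log axis) in 4 cell classes, 1 point per library. In basal cells, fibroblasts and macrophages both te2 points lie below both sham points, and Spink1 alone changed there by -3.76, -3.48 and -4.57 on the log2 scale.

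With all kept cells summed per library, changes of the mix of cells and changes within cells add up. Fxyd4 rose by 6.16 ± 0.18, Psca by 6.98 ± 0.71 and Wfdc18 by 6.61 ± 0.66, and Smr2l, Smr2 and Spp1 reached 652 ± 186, 311 ± 202 and 161 ± 118 CPM in te2 and are in neither sham table. Psca and Wfdc18 are each in the table of 1 sham library. The immunoglobulin genes Igkc (-7.55 ± 1.52) and Ighm (-4.09 ± 0.47) fell, though the sham mean of Igkc, 418 CPM, had an SD of 483. Itpripl2 (-4.36 ± 0.24) and the hemoglobin genes Hba-a1 (-4.11 ± 0.32), Hba-a2 (-4.08 ± 0.33) and Hbb-bs (-4.08 ± 0.40) fell as well. Of 13955 genes, 2928 passed, 1688 higher and 1240 lower. The count was 590 without te2 replicate 1 and 395 without te2 replicate 2, and without TMM factors the split was 3422 higher and 706 lower.

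The share of each class among kept cells was compared last. Basal cells made up 8.68% ± 4.25 of kept cells in sham and 22.9% ± 2.27 in te2 (adjusted p = 0.161 by edgeR). Unnamed cells made up 31.3% ± 10.4 and 11.6% ± 2.47 (0.161), most of them in sham in a cluster led by Hbb-bs, Hba-a1, Hba-a2, Spink1 and Sbp (524 and 422 sham, 22 and 40 te2 cells), fibroblasts 9.17% ± 7.03 and 4.58% ± 1.61 (0.330), luminal and proximal luminal cells together 45.7% ± 14.7 and 54.1% ± 5.48 (0.816), and macrophages 3.17% ± 0.238 and 4.44% ± 0.701 (0.810). T cells made up 1.14% ± 0.482 and 1.45% ± 0.39 (0.816), and lymphatic endothelial cells 0.829% ± 0.748 and 0.873% ± 0.555 (0.880). No share passed the test at these settings. The minimum of 500 UMIs per cell and the gap in depth between the groups can set these shares, as 72.0% and 65.4% of the deposited sham cells and 74.4% and 72.9% of the te2 cells were kept. Without sham replicate 2 the basal, fibroblast and unnamed shares passed the test (log2 ratios 2.01, -1.63 and -1.74), and without sham replicate 1 the fibroblast ratio turned to 0.12. With the stricter cell filter, which left the basal cluster of sham (35 and 110 cells) unnamed, the basal (7.12), macrophage (1.93), unnamed (1.35) and luminal and proximal luminal (-1.06) ratios passed, and the basal one passed by marker score (2.30). At resolution 0.5, where a cluster led by Hbb-bs counts as luminal, the luminal and proximal luminal ratio was -0.25.

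**Figure D5:**
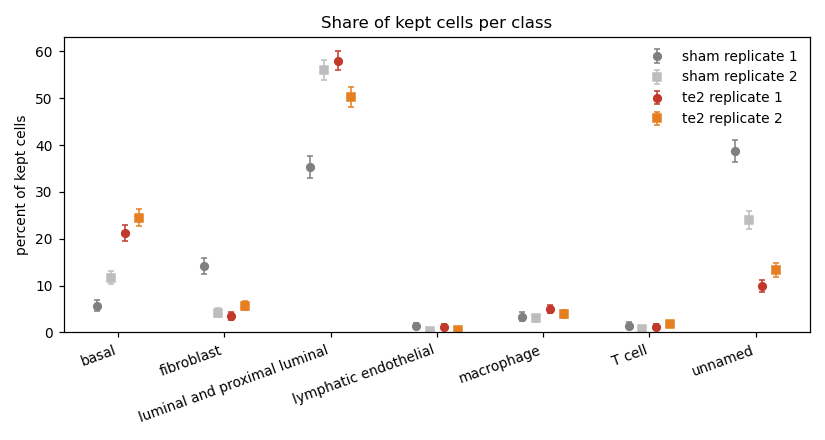
Points give the percent of kept cells in each class (vertical axis, from 0) for the 4 libraries, with exact 95% binomial intervals that cover counting error only. Basal cells made up 5.68% and 11.7% of the sham libraries and 21.3% and 24.5% of the te2 libraries, and no class passed the test.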

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

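The tests of free RNA and of proximal cells counted as luminal were chosen after the results were seen. The sign tests over the 12 luminal genes were added after their values were seen, and the tests by single cells and by depth were fixed before theirs. Groups of 2 libraries are too small for a test of a single library standing apart.

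The response to te2 differed between cell classes by edgeR's test of the class and treatment term. Against luminal cells, 835 of 12105 genes differed in proximal luminal cells, 279 of 11580 in basal cells, 145 of 11319 in fibroblasts and 120 of 10734 in macrophages. The proximal luminal count was 298 without sham replicate 2, 272 without te2 replicate 1 and 315 without te2 replicate 2. The basal count was 106, 108 and 93 without those libraries. The fibroblast count was 87 without sham replicate 1, 77 without te2 replicate 1 and 56 without te2 replicate 2. The macrophage count was 5 without sham replicate 1, 14 without sham replicate 2, 65 without te2 replicate 1 and 188 without te2 replicate 2. Without the library as a block the 4 counts were 294, 108, 84 and 63. In luminal, proximal luminal and basal cells and in fibroblasts most cells of the 2 groups lay in different clusters, so these differences compare those clusters too.

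The change of the metallothionein gene Mt1 was more negative in luminal cells than in each of the 4 other tested classes. The log2 change of Mt1 was -2.11 in luminal cells and 0.16 in proximal luminal cells, a difference of 2.38 ± 0.16, and that of Mt2 differed by 2.96 ± 0.19. In basal cells the differences were 1.95 ± 0.16 for Mt1 and 1.93 ± 0.18 for Mt2, and for Mt1 they were 2.04 ± 0.29 in fibroblasts and 2.30 ± 0.35 in macrophages. In proximal luminal cells the change of Defb50, a beta-defensin gene, was more positive by 2.67 ± 0.19, that of Papss2 by 2.03 ± 0.15 and that of Mat2a, which encodes an enzyme making S-adenosylmethionine, by 2.13 ± 0.17. The changes of Krt7 (-4.75 ± 0.27), Ahnak (-3.51 ± 0.19), Clu (-2.84 ± 0.15) and Cxcl17 (-3.12 ± 0.19) were less positive in proximal luminal than in luminal cells. Cyp2f2 rose in luminal cells and fell in proximal luminal cells, a difference of -3.32 ± 0.18. Clu, Cxcl17 and Cyp2f2 are among the genes that mark te2 proximal luminal cells in the tests below. For Krt7 and Ahnak, proximal luminal cells counted as luminal stay open there. Such cells are thus an open cause of the luminal rises of these 5 genes, also where they are set against other classes below. The same holds there for Lcn2, Ly6a and Ly6c1.

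Between basal and luminal cells, the inositol transporter gene Slc5a3 differed by 3.45 ± 0.32, Defb1 by 2.39 ± 0.26 and Cpe, a carboxypeptidase gene, by 6.68 ± 0.74. The cyclin gene Ccnd2 rose in luminal cells (3.92) and fell in basal cells (-1.34), a difference of -5.16 ± 0.22. Ahnak differed by -4.48 ± 0.22, Spink1 by -3.21 ± 0.15 and Sbp by -2.74 ± 0.15. Lcn2, with 3 counts in sham luminal cells, differed at an adjusted p of 4.03e-41. P-values of these differences, here and for the other classes, rest on a spread pooled over genes. With 2 libraries per group they do not measure how far each gene varies between animals.

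Between fibroblasts and luminal cells, the collagen gene Col6a3 differed by 2.96 ± 0.25, Creb5 by 2.98 ± 0.31 and Itpripl2 by 4.25 ± 0.57, and Ccnd2 by -4.34 ± 0.32, Ahnak by -3.85 ± 0.28, Ly6a by -4.38 ± 0.33 and Mgst1 by -3.09 ± 0.32. Ctla2a and Ly6c1, each with at most 3 counts in 1 group, differed at an adjusted p of 1.34e-12 and 1.67e-38. Between macrophages and luminal cells, the cathepsin genes Ctsl and Ctsd differed by 5.02 ± 0.43 and 2.97 ± 0.37, Itpripl2 by 5.64 ± 0.57, Spink1 by -3.72 ± 0.33, Sbp by -2.87 ± 0.32, Ahnak by -3.49 ± 0.41, Clu by -4.77 ± 0.60 and Cdcp3 by -2.38 ± 0.41. Fabp5 and Ighm, each with at most 3 counts in 1 group, differed at an adjusted p of 1.31e-20 and 1.73e-13. Ighm, an immunoglobulin gene, had 206 counts in sham luminal cells and 0 in te2. It did not pass the filter on low counts in luminal cells, so its change there was not tested by itself.

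Sbp and Spink1 transcripts were lower in te2 in basal cells, fibroblasts and macrophages alike, and hemoglobin transcripts in fibroblasts and macrophages. The ratio used below holds Sbp and Spink1 alone, so it does not address the source of hemoglobin transcripts. Free RNA with the make-up of the kept luminal cells is argued against in sham, where the luminal ratio of Sbp to Spink1 counts (1.85 and 1.95) was 1.96 and 1.46 times the highest of the 3 classes, beyond counting error. Free RNA of another make-up would keep 1 ratio over the 3 classes, and in sham the highest was 1.14 and 1.06 times the lowest (the share of these genes 1.42 and 1.30 times), but fibroblasts (95% interval 0.795 to 0.867) and macrophages (0.870 to 1.02) of sham replicate 1 lay apart. In te2 replicate 1 the ratio ran from 0.989 to 1.11 over the classes with overlapping intervals, and in te2 replicate 2 from 1.14 to 3.67, which 1 source would not give. Free RNA that is lower in te2 and a change inside these cells under te2 cannot be told apart, since neither a common ratio nor a wide gap between classes was found in both sham libraries.

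The 12 named genes that rose in luminal cells are mostly abundant in te2 proximal luminal cells. Free RNA from those cells would reach every class. In the te2 libraries the luminal level was a median of 2.33 and 0.507 times the higher of fibroblasts and macrophages. It was 13.6 and 4.14 times the lowest of 3 classes, with 10 and 8 of the 12 genes over 2 times (exact sign test p = 0.0386 and 0.388). Such free RNA is argued against for 8 genes, Psca, Smr2l, Ly6c1, Saa1, Krt7, Ly6a, Lrg1 and Olfml3. They had a class below the luminal level by over 2 times and beyond counting error in both libraries. For Smr2l in te2 replicate 1 that class was fibroblasts with 2 counts (6.55 times, interval 1.03 to 496). Its luminal level was 1.42 and 2.10 times that of macrophages, within counting error, so the argument is weak for Smr2l. Free RNA cannot be told apart from a rise in luminal cells for the 4 others, which lacked such a class in at least 1 library. Cells of the clusters named proximal luminal counted as luminal, or doublets with them, are argued against for 1 gene, Psca. It stood at 3.19 and 2.24 times the most that the genes marking each proximal cluster allow such cells to bring. For the 11 others such cells stay open. An unnamed cluster led by Psca (0 and 1 sham, 77 and 149 te2 cells) had its highest marker excess in luminal and the next in proximal luminal markers. That cluster was not bounded, so cells of its kind among the luminal cells stay open for Psca too. Over all 12 the named genes stood at 1.70 and 1.41 times the share of their proximal level that 11 genes marking proximal luminal cells reached. Both values lie under the limit of 2 set for that test, which is the outcome set for proximal luminal cells counted as luminal as the cause. With the luminal cells richest in these marking genes left out (105 of 446 and 86 of 456), the named genes kept a median of 61.6% and 67.1% of their level, which met the limit of 50% set beforehand against such cells as the cause, but 7 and 9 of 12 genes lay above it (exact sign test p = 0.774 and 0.146), too few to decide. A change within luminal cells under te2 stays open for all 12 genes, of which Krt7, Psca, Ahnak, Olfml3, Anxa3, Lcn2 and Lrg1 kept more than 50% in both libraries and Fxyd4, Ly6c1 and Ly6a in neither.

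Luminal cells had the most genes past the test. Their sums were also among the deepest, and when thinned to the totals of another class they called 1334 genes against 1096 in proximal luminal cells, 817 against 973 in basal cells and 285 against 307 in macrophages, so depth is a candidate cause of those gaps. Thinned to the totals of fibroblasts, luminal sums still called 465 genes against 113, so depth is not the whole cause of that gap. In 1 te2 library the luminal total already lay below the proximal luminal one. A weaker response of fibroblasts to te2 stays open as untested.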

How the results depend on the processing

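Some alternatives were chosen after the data were seen. They included the pooled luminal class, the class without its Msmb cluster, macrophages without their Spp1 cluster and the proximal cluster with most sham cells. A further alternative counted as luminal the unnamed clusters led by Hbb-bs (524 and 422 sham, 22 and 40 te2 cells) and by Psca (0 and 1 sham, 77 and 149 te2 cells). Of 1379 values that alternatives gave for the 86 named genes past the test, 1317 kept direction and threshold, 62 missed the threshold and 0 changed sign. Most of these genes were picked from the same data for large changes past the test, so they were likely to keep both. Among all genes past the test, DESeq2 also called 50.3%, 48.4%, 25.5%, 46.0% and 25.4% in luminal, proximal luminal, basal, fibroblast and macrophage sums. With secreted products left out these were 99.7%, 99.5%, 99.1%, 97.3% and 95.4%. Genes that an alternative left below its filter on low counts, or in a class too small to test, gave no value and are not among the 1379. Examples are the named rising macrophage genes without the Spp1 cluster and most named rising proximal luminal genes in the cluster with most sham cells. Of the 62, 12, 17, 7 and 7 came from leaving out sham replicates 1 and 2 and te2 replicates 1 and 2. Resolution 0.5 and 2 left the same cells in the fibroblast class, as did resolution 2 in the macrophage class. Those settings test nothing there, and their 38 values are not counted. The smallest sham sums held 48393 UMIs in macrophages, 89248 in fibroblasts and 91711 in basal cells, which limits what these classes can show. The causes of the moves below were not tested, except where fewer counts or cells entered.

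DESeq2 called 1806 genes in luminal cells, 539 in proximal luminal cells, 248 in basal cells, 62 in fibroblasts and 80 in macrophages. Thinning to equal totals gave 348, 279, 35 and 146 in the classes other than luminal. Classes by marker score gave 331 in basal cells, 62 in fibroblasts and 166 in macrophages. Fibroblasts had 233 without a filter on low counts, 175 without a cell filter and 50 with a stricter one. Macrophages had 512 without a cell filter, 177 at 10 CPM or more and 158 without the Spp1 cluster. The proximal cluster with most sham cells gave 187. The stricter cell filter left 1 and 11 cells in the smallest basal and macrophage sums, so it gave no value. Without TMM factors the median change of all genes moved to 0.10 in luminal cells and 0.25 in all cells summed.

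With 1 library left out, the group with 1 library left is assumed to vary like the other. Counts ran from 1962 to 3402 in luminal cells, 517 to 1133 in proximal luminal cells, 336 to 793 in basal cells, 0 to 205 in fibroblasts (443 at an unadjusted p under 0.05 where edgeR called 0), 107 to 246 in macrophages and 395 to 4356 in all cells. Lists past the test ran from 4 to 9 in basal cells and 3 to 10 in macrophages. Differences against luminal cells ran from 272 to 651, 93 to 208, 56 to 107 and 5 to 188 in proximal luminal cells, basal cells, fibroblasts and macrophages. Without the library block they were 294, 108, 84 and 63, and at 10 CPM or more 73 in macrophages.

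With an estimated correlation camera called 0 lists in each of the 5 classes, but on simulated data that setting found no raised list either, so it says nothing about stability. Simulated genes varied independently. In the data the estimated correlation was 0.546 for luminal cell cycle, 0.412 for proximal luminal unfolded protein response and -0.0837 for luminal acute phase genes. The preset 0.01 was thus not tested on lists whose members vary together. Fry, which asks whether a list moves and not whether it stands apart, called 6 lists in luminal cells, with polyamine and citrate metabolism and prolactin response among them, which camera did not call, 0 in proximal luminal cells, 1 in basal cells (TGF-beta targets, which camera did not call either), 0 in fibroblasts and 0 in macrophages. At 10 CPM or more, macrophages had 10 lists.

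Log2 ratios of shares moved too. With the stricter cell filter they were 7.12 for basal cells, 1.93 for macrophages, -1.06 for luminal and proximal luminal cells and 1.35 for unnamed cells, and these passed the test (adjusted p = 0.000275, 0.0206, 0.0306 and 0.0206). Under that filter the basal cluster of sham, 35 and 110 cells, stayed unnamed. Luminal and proximal luminal cells turned to -0.25 without a cell filter, -0.25 with doublets kept, -0.25 at resolution 0.5 and -0.54 at resolution 2. Unnamed cells turned to 0.023, 1.56, 0.074 and 2.07 under these settings. By marker score the ratio was 2.30 for basal cells (adjusted p = 0.0429), -0.31 for lymphatic endothelial and -0.17 for T cells, and lymphatic endothelial cells were at -0.44 without a cell filter. With 1 library left out, ratios ran from 0.97 to 2.01 for basal cells, -1.63 to 0.12 for fibroblasts, -0.050 to 0.62 for luminal and proximal luminal cells, -0.76 to 1.54 for lymphatic endothelial cells, -0.032 to 0.85 for T cells and -1.74 to -1.05 for unnamed cells.

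Of the receptor genes that missed the test, Esr2 in luminal cells passed by marker score (-1.27) and with proximal luminal cells pooled in (-1.37, edgeR adjusted p = 0.0169). It also passed with the unnamed clusters led by Hbb-bs and by Psca counted as luminal (-1.07, adjusted p = 0.0475). Without the Msmb cluster it missed the threshold (-0.84, adjusted p = 0.149). Its change was -1.21 without sham replicate 1. Esr1 in basal cells passed by marker score (-2.28). Esr1 in luminal cells turned to 0.10 without TMM factors, 0.024 without a filter on low counts, 0.27 with the stricter cell filter, 0.12 without a cell filter, 0.17 at resolution 2 and ran from -0.43 to 0.33 with 1 library left out. Prlr there turned to 0.035 without TMM factors and 0.013 with doublets kept, and ran from -0.22 to 0.070 with 1 library left out. Prlr in fibroblasts turned to -0.41 by marker score and ran from -0.033 to 0.46 with 1 library left out.

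Replicate numbers only name the animals. With the number as a replicate block, 3675, 1225, 896, 99 and 254 genes passed in luminal, proximal luminal, basal, fibroblast and macrophage sums and 2051 in all cells. Deviations of libraries with the same number correlated across genes, which are not independent, at -0.07, -0.02, -0.01, -0.06 and 0.10 in the 5 classes.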

Other observations

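Within the proximal luminal cluster that holds most sham cells, a comparison added after the data were seen, 187 genes passed edgeR's test, 98 higher and 89 lower in te2. Of these, 151 are among the 1096 of the whole class, and 150 changed in the same direction in both. Upk1a (-2.58), Car2 (-2.99) and Creb5 (-2.12) fell there too, as did Meis2 and Naip5, with 137 and 122 counts in sham and 1 and 3 in te2, and Igfbp5 missed the threshold (-1.47, adjusted p = 0.0556). Saa1 rose there from 0 to 21 counts (adjusted p = 2e-09). The other named rising genes of the class and Prlr did not pass the filter on low counts in this cluster, with 6 counts of Smr2l, 7 of Smr2, 3 of Dmbt1, 0 of Ltf and 9 of Ly6c1 in te2, so their rises were not tested within it. Prlr had 6 and 32 counts there among 157373 and 511481 UMIs of the sham libraries. In the te2 libraries it had 16 and 2 counts among 60036 and 38327 UMIs. The sums held 668854 UMIs in sham and 98363 in te2. The share of cells from each library in this cluster was not compared.

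Some luminal lists moved both ways or missed camera. Of 20 genes of polyamine and citrate metabolism, 6 rose and 7 fell in luminal cells, the same adjusted over the list alone (camera adjusted p = 0.379; fry, which asks whether a list moves on balance 1 way, adjusted p = 0.0145, downward). Of 29 secretion machinery genes, 9 rose and 4 fell (10 and 5 adjusted over the list alone; adjusted p = 0.324). Of 26 genes of cholesterol and fatty acid synthesis, 4 rose and 7 fell (5 and 7 adjusted over the list alone; adjusted p = 0.800). Their median was above 0 while the test pointed down. Of 24 unfolded protein response genes, 7 rose and 4 fell (8 and 5 adjusted over the list alone; adjusted p = 0.530).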
